A study of Rattus norvegicus with 6 samples.

How the data were processed

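Gene expression was measured in gastrocnemius muscle of male Sprague-Dawley rats with Affymetrix Rat Gene 1.0 ST arrays, which carry probes across the whole transcript of each gene, after biotin labelling of total RNA. The rats were 12 weeks old when the diets began and 20 weeks old when the muscle was taken, after 8 weeks of free access. They were diet-induced obese, and the diets were rich in fat and sucrose. Every diet held 4.6 kcal/g with 10% of its energy from protein, per the design text. In the control diet the protein was casein. In the dairy diet it was complete dairy protein from skim milk powder, and in the leucine diet 7.1% of the energy came from casein and 2.9% from free leucine. The design text gives 4 rats per diet, and the series holds 2 arrays per diet, 6 in all. Per the labels, nothing states whether the arrays of a diet came from separate rats, so each p-value measures only the spread between these samples. The labels name gastrocnemius as the tissue of every array, while the protocol texts speak of liver in the storage and RNA extraction steps.

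The deposited values were log2 signals, 1 per array and transcript cluster, made by the authors with Affymetrix Expression Console per the submitters' processing notes. The version of that software and its background correction, normalization and summarization were not given in the sources used here. The log2 scale was checked on the values, which ran from 1.14 to 13.7 with a median per array between 3.46 and 3.56. Scanner files and background readings were not analysed here.

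The deposited table held 29214 transcript clusters. Of these, 15633 had a gene entry in the platform annotation, 323 had several genes and 15310 had 1. Current gene symbols were taken from the gene identifier for 15279 clusters and from a sequence accession for 6, and the platform symbol was kept for 25. Where several clusters carried the same symbol, which was so for 527 genes, the cluster with the highest mean over the 6 arrays was used. This left 14506 genes for the tests, with no filter on dim genes. In 124 genes the values were identical on all 6 arrays.

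Each of the 3 pairs of diets was compared with limma 3.58.1 in R 4.3.3. A single linear model with diet as its only term was fitted to all 6 arrays, which left 3 residual degrees of freedom, and the variances were moderated by empirical Bayes. The p-values were adjusted by Benjamini-Hochberg over the 14506 genes, with a threshold of 0.05. The replicate numbers were checked for pairing by correlating, across genes, the differences between arrays 1 and 2 of each diet. These correlations were 0.0865 between casein and dairy, 0.179 between casein and leucine and 0.0536 between dairy and leucine. They were not all above 0.1, so the numbers were not taken to pair the samples. Log2 fold changes are given with the standard error of the model (n = 2 arrays against 2), and levels with the SD over the 2 arrays of a diet.

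In all, 34 gene lists were tested, covering muscle fibre types, amino acid and energy metabolism, protein turnover, stress and immune pathways, and markers of the other cell types that a piece of muscle can hold. Of their 934 symbols 832 were measured, 2 of them found through a synonym. The camera test of limma was run with a preset correlation between genes of 0.01, and its p-values were adjusted over the 34 lists within each comparison with a threshold of 0.05. Camera with the correlation estimated from the arrays, and fry, which tests whether the genes of a list move on balance in 1 direction, were run beside it. Camera asks whether a list is shifted relative to the other genes, and its 2 forms are named wherever their calls differ. The relation between the responses to leucine and dairy was described by the correlation of their fold changes across genes. Since both comparisons use the same casein arrays, 100 simulations with unchanged diets and shared controls were set beside it.

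The lists, the tests, the thresholds, the alternatives and the rule for naming genes were chosen before the data were examined. By that rule, each comparison names up to 10 higher and 10 lower genes past the threshold whose arrays do not overlap between the diets. Where fewer pass, up to 8 per direction with the smallest p among genes whose mean level lies above the median gene are named as not past the threshold. Their arrays also had to lie apart between the diets, so that separation is by construction. For each list past the camera threshold, up to 4 members with the smallest p in the direction of the list were added. Members so named move with their list by construction. In the comparisons with casein 14 genes were fixed in advance. Any gene named outside this rule is said to have been chosen after its values were seen.

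The procedure was tested on simulated data for leucine against casein with all 14506 genes, in 10 runs with 200 changed genes each. It recovered 46.4% of genes changed 2-fold, 80.6% of those changed 4-fold and 87.9% of those changed 8-fold, with a median of 6.5 false calls per run. In these runs each gene varied independently with its own residual SD, and no array was made to stand apart. The rates therefore do not show that genes not called in the data were unchanged. The tricarboxylic acid cycle list, shifted by 0.25 on the log2 scale, was called by camera with the preset correlation in 95% of separate runs with independent genes. In draws without an effect in which genes varied together, described next, the same list was called in 54%. With no effect and independent genes, a median of 0 and at most 1 of the lists were called in 100 draws.

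A control for chance list calls was chosen after seeing the data: 100 draws without a diet effect that kept the way genes varied together between arrays of a diet. Camera with the preset correlation then called a median of 10 lists and at most 15, with 14 or more in 18 draws and 10 or more in 54. By list the share of draws with a call was 77% for hepatocytes, 71% for oxidative phosphorylation and 70% for slow fibres. It was 64% for fatty acid oxidation, 61% for macrophages, 59% for inflammation and 55% for interferon. For the tricarboxylic acid cycle and branched-chain catabolism it was 54% each, and 48% for fast fibres. Ribosomal proteins stood at 42%, the matrix at 39%, glycolysis at 35% and mitochondrial biogenesis at 14%. For the mTORC1, ATF4, atrophy, calcium-handling and Schwann cell lists the share was 0%. The draws on 6 arrays were simulated as leucine against casein, with every array drawn in the same way, and were used for every comparison. Camera with the estimated correlation called 0 in every draw. Its power to call a shifted list on so few arrays was not tested. Its 0 calls therefore do not show that lists were unchanged. With only the leucine and dairy arrays, the draws called a median of 5 lists and at most 9. These draws rest on the few differences between arrays of a diet, and casein array 2 against casein array 1 was the largest of them. The count of draws in which a list median lay as far from 0 as in the data is given beside the lists described first.

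The alternatives were quantile normalization, centring of each array on its median, the brighter genes alone, every transcript cluster, trended robust moderation, array weights, the 4 arrays of the compared diets alone, a threshold of 0.10, a replicate block and each array left out in turn. Chosen after seeing the data, camera with an estimated correlation was also run on the 4 arrays of the compared diets and without either casein array. The number of arrays limits the precision of every value. The transcript clusters without a single gene name were left out of the gene tests because they could not be assigned to a gene.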

Results

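Muscle RNA was profiled on 6 arrays, 2 from rats fed casein, 2 from rats fed dairy protein and 2 from rats fed casein with added leucine. The deposited log2 signals had medians between 3.46 and 3.56 per array, and 14506 genes were compared. Transcripts of fast fibres, the main fibre type of gastrocnemius, stood at a median level of 12.4, at percentile 99.9 of all genes. Hepatocyte transcripts, examined because the protocol texts mention liver, stood at a median level of 4.25 and at percentile 51.4, with percentiles between 34.0 and 75.3 on single arrays. The mean correlation with the other arrays was 0.974 for casein array 2 and between 0.985 and 0.988 for the rest. On casein array 2, 177 genes were over 2-fold above every other array and 64 were over 2-fold below. Its slow-fibre transcripts had a median of −2.85 relative to their gene means, its hepatocyte transcripts a median of 1.94 and its inflammatory transcripts a median of 0.62. Because this array is 1 of the 2 controls, the medians of the gene lists compared with casein are given with and without it.

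**Figure D1:**
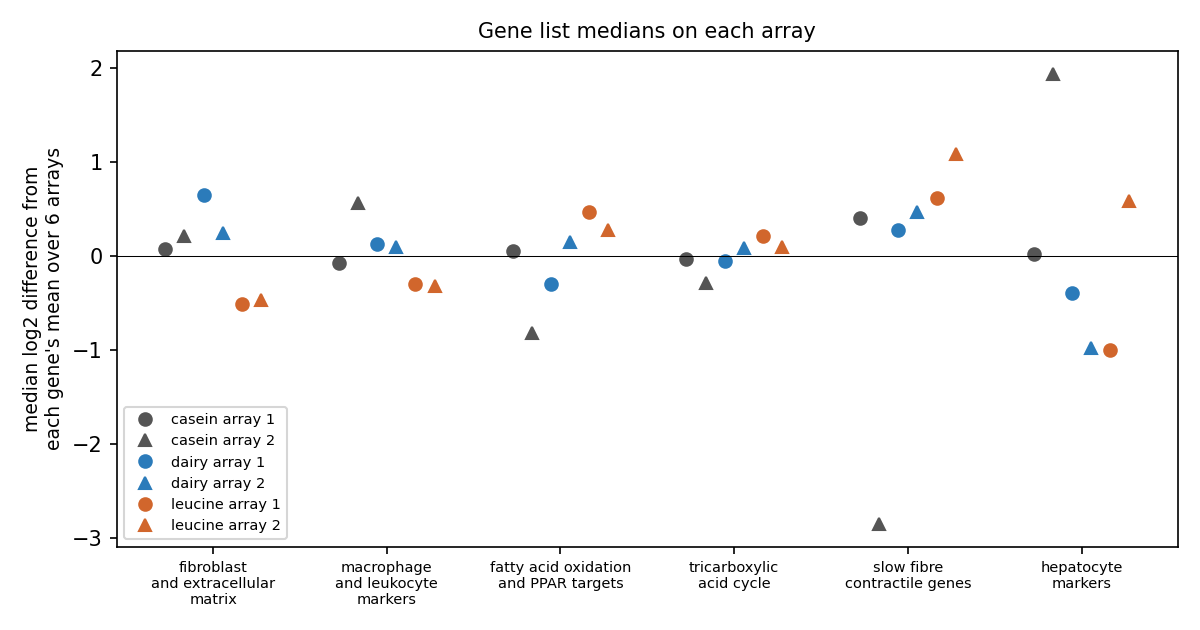
Median log2 difference of 6 gene lists on each array (vertical axis) from the mean of each gene over the 6 arrays; each point is 1 array, coloured by diet, with circles for array 1 and triangles for array 2. The matrix list lies at −0.51 and −0.47 on the leucine arrays and above 0 on the other 4, and the slow-fibre list lies at −2.85 on casein array 2.

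The first comparison asked what the replacement of part of the casein by free leucine changed. Transcripts of fibroblasts and the extracellular matrix were lower with leucine in 19 of 20 measured genes, with a median log2 fold change of −0.58. Col1a1, a chain of type I collagen, stood at 6.80 ± 0.16 with leucine and 8.74 ± 0.33 with casein (SD, n = 2 each), a log2 fold change of −1.94 ± 0.27 (SE), or 3.84-fold lower. Mmp2, a gelatinase that degrades collagen, had a log2 fold change of −0.93 ± 0.14, and Col4a1, a collagen of basement membranes, one of −0.54 ± 0.09. Macrophage and leukocyte markers were lower in 23 of 23 genes, with a median of −0.56. Among them were C1qb, a chain of complement C1q, at −1.08 ± 0.20 and Cd74, the invariant chain of class II antigen presentation, at −1.15 ± 0.34, or −0.66 without casein array 2. By camera with the preset correlation the matrix list was shifted down with an adjusted p = 3.91e-10 and the macrophage list with an adjusted p = 2.98e-06. For both the adjusted p = 0.600 with an estimated correlation. In the matrix list 0 genes passed over all genes, 12 had an unadjusted p under 0.05 and 11 passed when adjusted over the list alone. In the macrophage list 1 gene, Tyrobp, passed adjusted over the list alone. Without casein array 2, on which macrophage markers had a median of 0.56 relative to their gene means, the matrix median was −0.50 and still past the camera threshold. The macrophage median was then −0.17 and not past it, and without casein array 1 it was −0.91. In draws without an effect, 2 of 100 had a matrix median and 3 of 100 a macrophage median as far from 0. Camera with the preset correlation called the matrix list in 39% of such draws and the macrophage list in 61%.

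Genes of fatty acid oxidation and targets of PPAR, the lipid-sensing nuclear receptors, were higher with leucine in 31 of 31 measured genes, with a median log2 fold change of 0.72. Lpl, the lipase that releases fatty acids from circulating triglyceride, was 2.25-fold higher (1.17 ± 0.24). Pdk4, a kinase that inhibits pyruvate dehydrogenase, was 2.69-fold higher (1.43 ± 0.32), and Hadhb, a subunit of the mitochondrial trifunctional protein, stood at 0.66 ± 0.18. Genes of the tricarboxylic acid cycle were higher in 20 of 20, with a median of 0.34, and those of oxidative phosphorylation in 60 of 68, with a median of 0.24. Cox7c of complex IV stood at 0.67 ± 0.09 and Sdhd of complex II at 0.56 ± 0.10. Mitochondrial biogenesis and energy sensing had 24 of 31 genes higher and a median of 0.25. Tfb2m, a mitochondrial transcription factor, stood at 0.71 ± 0.10 and Ppara at 1.03 ± 0.26. Branched-chain amino acid catabolism had 19 of 23 genes higher and a median of 0.23, with Auh, a hydratase of leucine breakdown, at 0.64 ± 0.11. The camera adjusted p was 1.43e-08 for fatty acid oxidation, 2.98e-06 for the tricarboxylic acid cycle, 1.06e-07 for oxidative phosphorylation, 0.00235 for mitochondrial biogenesis and 0.00114 for branched-chain amino acid catabolism. In all 5 the adjusted p = 0.600 with an estimated correlation. The preset correlation called them, in the same order, in 64%, 54%, 71%, 14% and 54% of draws without an effect. Over all genes 0 members passed, and adjusted over the list alone only Tfb2m did. Without casein array 2, on which fatty acid oxidation genes had a median of −0.81 relative to their gene means, the medians were 0.39 for fatty acid oxidation and 0.16 for the tricarboxylic acid cycle, both past the camera threshold. Those for oxidative phosphorylation at 0.03, mitochondrial biogenesis at 0.08 and branched-chain amino acid catabolism at 0.13 were not past it. Mitochondrial biogenesis was also not past it without leucine array 1, at 0.12. Without casein array 1, and so against casein array 2 alone, the medians of fatty acid oxidation and oxidative phosphorylation were 1.12 and 0.51. Draws without an effect had a median as far from 0 in 4 of 100 for fatty acid oxidation, 1 for the tricarboxylic acid cycle, 9 for oxidative phosphorylation, 0 for mitochondrial biogenesis and 11 for branched-chain amino acid catabolism.

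Interferon-response genes were lower with leucine in 21 of 26, with a median of −0.46, and Isg15, a ubiquitin-like protein induced by interferon, was 2.05-fold lower (−1.03 ± 0.16). Inflammatory cytokines and NF-kB targets were lower in 19 of 22, with a median of −0.41. Schwann cell and nerve markers were lower in 10 of 12, with a median of −0.20, and Pmp22, a myelin protein, stood at −1.30 ± 0.18. The median level of these markers was low, 3.07 at percentile 33.0 of all genes, and 2 of the 12 lay above the median gene. Slow-fibre contractile genes were higher in 14 of 14, with a median of 2.01, and Myoz2, a sarcomeric protein of slow fibres, stood at 2.75 ± 1.11, or 1.16 without casein array 2 and 4.34 without casein array 1. Fast-fibre genes were lower in 13 of 15, with a median of −0.11. Hepatocyte markers were lower in 25 of 25, with a median of −1.08. Genes of mTORC1 and amino acid sensing were higher in 26 of 35, with a median of 0.12. The camera adjusted p for these lists was 0.00127 for interferon, 0.0202 for inflammation, 0.00620 for Schwann cells, 0.000452 for slow fibres, 0.00761 for fast fibres, 0.000331 for hepatocytes and 0.0318 for mTORC1. With an estimated correlation the adjusted p = 0.604 for interferon, 0.621 for slow fibres, 0.630 for inflammation, fast fibres and hepatocytes, and 0.600 for Schwann cells and mTORC1. Adjusted over the list alone, Pmp22, the fast-fibre gene Myoz1 (−0.35 ± 0.06) and Slc38a9 passed, and 0 passed over all genes. Without casein array 2 the interferon median was −0.21, the Schwann cell median −0.09 and the fast-fibre median −0.28, all past the camera threshold. Without that array the slow-fibre median was 0.06, the hepatocyte median −0.27, the inflammatory median 0.01 and the mTORC1 median 0.02, none past it. Other single arrays also decided calls. Without leucine array 1 the hepatocyte median was −0.40, the inflammatory median −0.31 and the mTORC1 median 0.08, none past the threshold. Without leucine array 2 the Schwann cell median was −0.21, the fast-fibre median −0.10, the inflammatory median −0.27 and the mTORC1 median 0.14, none past it, and the hepatocyte median was −1.94. Without casein array 1 the fast-fibre median of −0.06 and the mTORC1 median of 0.16 were not past it. The slow-fibre median was then 3.66, the hepatocyte median −1.91 and the inflammatory median −0.82. Draws without an effect had a median as far from 0 in 3 of 100 for interferon, 8 for inflammation, 0 for Schwann cells and mTORC1, 10 for slow fibres, 41 for fast fibres and 23 for hepatocytes. Camera with the preset correlation called hepatocytes in 77% of such draws, slow fibres in 70%, inflammation in 59% and interferon in 55%. Fast fibres were called in 48%, and Schwann cells and mTORC1 in 0%.

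Among single genes, those with the smallest p that were higher with leucine included Kcnma1, the pore subunit of the large-conductance calcium-activated potassium channel, at 1.14 ± 0.08, and Nqo2, a quinone reductase, at 1.01 ± 0.07. Slc38a9, the lysosomal arginine sensor of mTORC1, stood at 5.16 ± 0.04 with leucine and 4.34 ± 0.05 with casein (SD, n = 2 each), a log2 fold change of 0.82 ± 0.06. Asrgl1, an asparaginase, stood at 1.01 ± 0.09, Slc6a8, the creatine transporter, at 0.65 ± 0.06, and Slc5a6, a transporter of biotin and pantothenate, at 0.75 ± 0.08. Among those lower, Thbs1, the matrix glycoprotein thrombospondin 1, was 3.33-fold lower (−1.74 ± 0.18) and Ly6e stood at −0.78 ± 0.10. Of the 14 genes fixed in advance, Pdk4 and Mstn, which encodes the growth inhibitor myostatin and stood at −1.44 ± 0.39, had the largest log2 fold changes. Bcat2, which starts branched-chain amino acid breakdown, stood at −0.41 ± 0.32, the complex subunit Bckdha at −0.06 ± 0.16 and its inhibitory kinase Bckdk at −0.12 ± 0.28. Mtor stood at 0.14 ± 0.12, the asparagine synthetase gene Asns at −0.54 ± 0.27 and the glucose transporter gene Slc2a4 at 0.26 ± 0.14. Irs1 stood at 0.26 ± 0.39, Ppargc1a at 0.39 ± 0.27, Cpt1b at 0.33 ± 0.27 and Ucp3 at 0.86 ± 0.44. The ubiquitin ligase genes Fbxo32 and Trim63 stood at 0.34 ± 0.26 and −0.20 ± 0.41. With casein array 2 left out, Bcat2 stood at −0.83, Bckdha at −0.24, Bckdk at 0.10, Mtor at 0.02, Asns at −0.16, Slc2a4 at 0.09, Irs1 at −0.01, Cpt1b at −0.06, Fbxo32 at 0.70 and Trim63 at 0.33. By limma 0 of 14506 genes passed, with a lowest adjusted p of 0.353, while 1394 had an unadjusted p under 0.05 (691 higher, 703 lower) against 725.3 by chance. At an adjusted p of 0.10 the count was also 0. When the casein side was casein array 2 alone, with the spread taken from the other diets, a single gene passed, Il6, with an adjusted p of 0.0445. Il6 stood at 6.97 on casein array 2 and at 2.0 to 2.40, below the array medians, on the other 5, so that call restates the outlying array. The lowest adjusted p was up to 0.542 with other arrays left out. In all 213 genes differed over 2-fold (71 higher, 142 lower), and in 31.5% of genes the arrays of both diets did not overlap, where chance gives 33.3%. Camera called 14 of 34 lists (7 up, 7 down), camera with an estimated correlation 0 and fry 0, and 18 of 100 draws without an effect had 14 or more calls.

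The second comparison asked what complete dairy protein in place of casein changed. Calcium-handling genes were higher with dairy in 24 of 25, with a median log2 fold change of 0.22. Among them were Hrc, a calcium-binding protein of the sarcoplasmic reticulum, at 0.27 ± 0.07 and Stim1, its calcium sensor, at 0.24 ± 0.09. Matrix genes were higher in 19 of 20, with a median of 0.30. Col3a1, the chain of type III collagen, stood at 7.89 ± 0.32 with dairy and 7.16 ± 0.06 with casein (SD, n = 2 each), 1.67-fold higher (0.74 ± 0.17). Genes of mTORC1 and amino acid sensing were higher in 25 of 35, with a median of 0.10 that was −0.025 after quantile normalization. Slc38a9 stood at 0.29 ± 0.06 and Nprl2, an inhibitor of mTORC1, at 0.43 ± 0.14. Hepatocyte markers were lower in 24 of 25, with a median of −1.54, and the liver enzymes Tat and Cyp2e1 stood at −1.54 ± 0.61 and −2.08 ± 0.87, or −0.65 and −0.83 without casein array 2. The camera adjusted p was 0.000955 for calcium handling, 0.000259 for the matrix, 0.0437 for mTORC1 and 1.05e-08 for hepatocytes. For each the adjusted p = 0.731 with an estimated correlation. By fry the calcium and mTORC1 lists passed, with adjusted p of 0.0190 and 0.0335. Without casein array 2, on which hepatocyte markers had a median of 1.94 relative to their gene means, the medians were 0.13 for calcium handling, 0.34 for the matrix and −0.74 for hepatocytes, all past the camera threshold, and 0.08 for mTORC1, not past it. Without casein array 1 the hepatocyte median was −2.57, and without dairy array 2 the matrix median was 0.50 and the mTORC1 median 0.05. The matrix list was also not past it without casein array 1, at 0.29, or dairy array 1, at 0.08, and the mTORC1 list was not past it whichever array was left out. Draws without an effect had a median as far from 0 in 0 of 100 for calcium handling and mTORC1 and in 13 for the matrix and for hepatocytes.

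Genes of oxidative phosphorylation were higher with dairy in 66 of 68, with a median of 0.20, those of the tricarboxylic acid cycle in 20 of 20, with a median of 0.16, and those of fatty acid oxidation in 30 of 31, with a median of 0.32. Cox7c stood at 0.29 ± 0.09, Sdhd at 0.31 ± 0.10 and Pdk4 at 0.74 ± 0.32. Slow-fibre genes were higher in 14 of 14, with a median of 1.58, and Myoz2 stood at 1.77 ± 1.11, or 0.18 without casein array 2 and 3.36 without casein array 1. Fast-fibre genes were higher in 13 of 15, with a median of 0.09 that was −0.021 after quantile normalization. Cytosolic ribosomal protein genes were higher in 52 of 67, with a median of 0.13 and Rpl30 at 0.45 ± 0.13. Glycolysis genes were higher in 24 of 28, with a median of 0.13 and Gapdh at 0.16 ± 0.06. Atrophy and autophagy genes were higher in 20 of 28, with a median of 0.12 and Atg12, which takes part in autophagosome formation, at 0.39 ± 0.08. Inflammatory genes were lower in 16 of 22, with a median of −0.38 and Il1b at −1.03 ± 0.44, or −0.39 without casein array 2. Amino acid response genes driven by ATF4 were lower in 19 of 26, with a median of −0.03 and Cth, an enzyme of cysteine synthesis, at −1.05 ± 0.32, or −0.60 without that array. The camera adjusted p was 2.26e-07 for oxidative phosphorylation, 0.00493 for the tricarboxylic acid cycle, 0.00799 for fatty acid oxidation, 0.00192 for slow fibres and 0.0452 for fast fibres. It was 0.00342 for ribosomal proteins, 0.0141 for both glycolysis and inflammation, 0.0432 for atrophy and 0.0437 for ATF4. With an estimated correlation the adjusted p = 0.762 for fatty acid oxidation, 0.824 for fast fibres and 0.731 for the others.

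Most of these lists moved with casein array 2. Without it the medians were 0.01 for oxidative phosphorylation, 0.03 for the tricarboxylic acid cycle, −0.11 for fatty acid oxidation, 0.03 for fast fibres, 0.05 for ribosomal proteins, 0.04 for glycolysis, 0 for inflammation and 0.00075 for ATF4, none past the camera threshold. The slow-fibre median was then −0.18 and past it in the other direction, and the atrophy median was 0.22 and past it. Without dairy array 1 the ribosomal median of 0.06, the glycolysis median of 0.08, the fast-fibre median of 0.0018, the atrophy median of 0.13 and the ATF4 median of −0.03 were not past it. Without dairy array 2 this held for the slow-fibre median of 1.38, the fatty acid oxidation median of 0.12, the tricarboxylic acid cycle median of 0.08, the inflammatory median of −0.27, the atrophy median of 0.15 and the ATF4 median of −0.10. The fast-fibre, inflammatory, atrophy and ATF4 lists were also not past it without leucine array 1 or leucine array 2, and atrophy at 0.04 was not past it without casein array 1. Without casein array 1 the medians were 3.10 for slow fibres, 0.77 for fatty acid oxidation, 0.43 for oxidative phosphorylation, 0.28 for the tricarboxylic acid cycle, 0.22 for fast fibres, −0.64 for inflammation and −0.08 for ATF4. Without dairy array 2 the fast-fibre median was 0.22 and the ribosomal median 0.20. Draws without an effect had a median as far from 0 in 6 of 100 for atrophy and in 12 or more for each of the other lists of this group.

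Single genes higher with dairy at the smallest p included Emcn, an endothelial sialomucin, at 6.08 ± 0.01 with dairy and 5.50 ± 0.02 with casein (SD, n = 2 each), a log2 fold change of 0.59 ± 0.06. Ache, the acetylcholinesterase of the neuromuscular junction, stood at 0.55 ± 0.06, Adamtsl4 at 0.61 ± 0.07, Asrgl1 at 0.76 ± 0.09, Prkx at 0.66 ± 0.08 and Slc6a8 at 0.45 ± 0.06. Ostn, which encodes the secreted peptide musclin, was 2.94-fold lower (−1.56 ± 0.28) and Thbs1 1.93-fold lower (−0.95 ± 0.18). Of the genes fixed in advance, Bcat2 stood at −0.64 ± 0.32, Mstn at −0.63 ± 0.39, Asns at −0.43 ± 0.27, Irs1 at 0.42 ± 0.39, Slc2a4 at 0.32 ± 0.14, Cpt1b at 0.29 ± 0.27, Ucp3 at 0.22 ± 0.44, Mtor at 0.21 ± 0.12 and Ppargc1a at 0.12 ± 0.27. Bckdha stood at −0.04 ± 0.16, Bckdk at 0.03 ± 0.28, and Fbxo32 and Trim63 at −0.08 ± 0.26 and −0.08 ± 0.41. With casein array 2 left out, Bcat2 stood at −1.06, Mstn at −0.25, Asns at −0.05, Irs1 at 0.15, Slc2a4 at 0.16, Cpt1b at −0.10, Ucp3 at 0.53, Mtor at 0.09, Bckdha at −0.22, Bckdk at 0.26, Fbxo32 at 0.28 and Trim63 at 0.45. By limma 0 of 14506 genes passed, with a lowest adjusted p of 0.833 and also 0 at an adjusted p of 0.10, while 696 had an unadjusted p under 0.05 (361 higher, 335 lower) against 725.3 by chance. Adjusted over the list alone 1 list member passed, Emcn among the endothelial markers, with an adjusted p of 0.00447. Against casein array 2 alone, again with the spread of the other diets, a single gene passed over all genes, the same Il6, with an adjusted p of 0.0379. The lowest adjusted p was up to 0.896 with other arrays left out. In all 136 genes differed over 2-fold (35 higher, 101 lower), and the arrays did not overlap in 23.2% of genes, where chance gives 33.3%. Camera called 14 of 34 lists (11 up, 3 down), camera with an estimated correlation 0 and fry 2. Of 100 draws without an effect, simulated for leucine against casein, 18 had 14 or more calls. The camera count for dairy against casein was 9 with the 4 dairy and casein arrays alone.

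The third comparison set leucine directly against dairy, in which the casein arrays enter only through the pooled variance. Matrix genes were lower with leucine in 20 of 20, with a median log2 fold change of −0.85. Col1a1 stood at 6.80 ± 0.16 with leucine and 8.80 ± 0.42 with dairy (SD, n = 2 each), 4.00-fold lower (−2.00 ± 0.27), and Col3a1 at −1.44 ± 0.17, Mmp2 at −1.22 ± 0.14 and Fn1, the fibronectin gene, at −1.96 ± 0.33. Macrophage and leukocyte markers were lower in 22 of 23, with a median of −0.55. Among them were Csf1r, the receptor of the macrophage growth factor CSF1, at −0.88 ± 0.16 and C1qb at −1.12 ± 0.20. Calcium-handling genes were lower in 19 of 25, with a median of −0.27. Calr, the calcium-binding chaperone calreticulin, and Camk2a, a calmodulin-dependent kinase, each stood at −0.44, with SE of 0.08 and 0.10. By camera the adjusted p was 2.01e-21 for the matrix, 2.75e-06 for macrophages and 0.000188 for calcium handling. The draws on 6 arrays, simulated for leucine against casein, had these lists called in 39%, 61% and 0%. With an estimated correlation the adjusted p = 0.358 for the matrix and calcium lists and 0.615 for macrophages. By fry calcium handling passed with an adjusted p of 0.00276 and the matrix list did not, with 0.0701. In the matrix list 0 genes passed over all genes, 15 had an unadjusted p under 0.05 and 14 passed adjusted over the list alone. In the macrophage list 3 passed adjusted over the list alone, Csf1r, C1qb and Tyrobp. In draws without an effect that used only these 4 arrays, 0 of 100 had a median as far from 0 for the matrix, macrophage or calcium list, and with all 6 arrays the counts were 0, 3 and 0. These 3 lists were past the camera threshold whichever array was left out, with matrix medians between −1.04 and −0.68. The calcium median was −0.17 without dairy array 1 and −0.17 without dairy array 2.

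**Figure D2:**
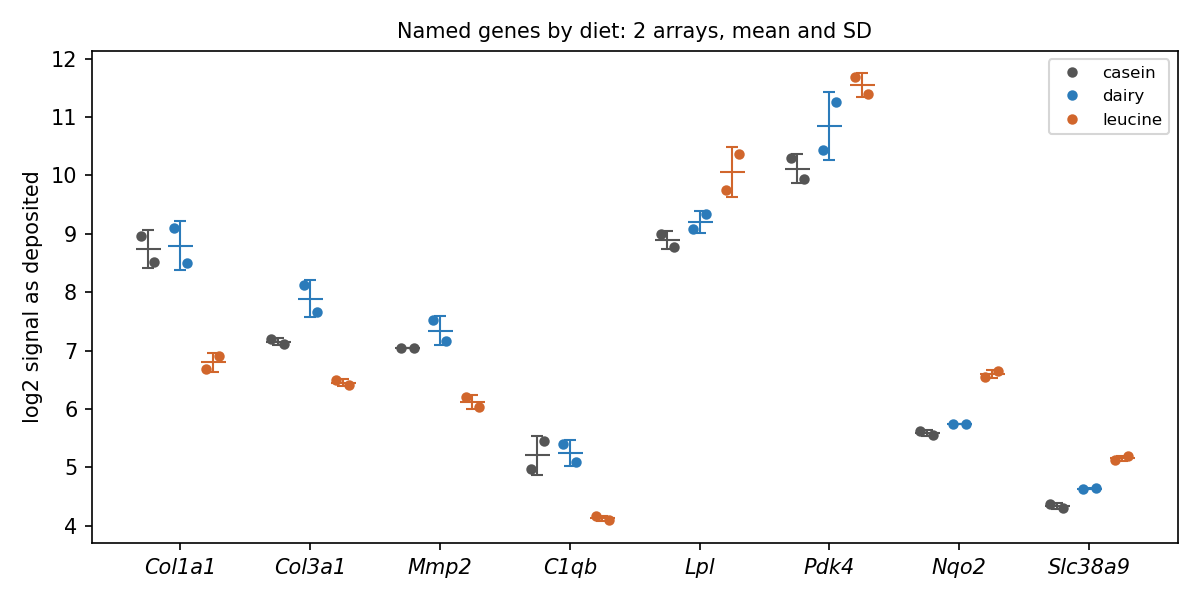
Deposited log2 signal (vertical axis) of 8 named genes by diet; points are single arrays, bars the mean and SD of the 2 arrays of a diet. Both leucine arrays lie below the other 4 arrays for Col1a1, Col3a1, Mmp2 and C1qb and above them for Lpl, Pdk4, Nqo2 and Slc38a9. Nqo2 and Slc38a9 were named by a rule that asks for arrays that do not overlap between the compared diets.

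Fatty acid oxidation genes were higher with leucine than with dairy in 30 of 31, with a median of 0.45, and Lpl stood at 0.85 ± 0.24 and Hadhb at 0.61 ± 0.18. Branched-chain amino acid catabolism genes were higher in 18 of 23, with a median of 0.23, and Acadsb, a dehydrogenase of short branched acyl-CoA, stood at 0.60 ± 0.20. Genes of the tricarboxylic acid cycle were higher in 16 of 20, with a median of 0.14 and Sucla2 at 0.29 ± 0.10. Cytosolic ribosomal protein genes were lower in 53 of 67, with a median of −0.18, and Rpl36 stood at −0.85 ± 0.18 and Rps26 at −0.62 ± 0.11. Glycolysis genes were lower in 22 of 28, with a median of −0.18 and Gapdh at −0.31 ± 0.06, and fast-fibre genes in 14 of 15, with a median of −0.27 and Myoz1 at −0.43 ± 0.06. Interferon-response genes were lower in 23 of 26, with a median of −0.34 and Isg15 at −0.88 ± 0.16. The camera adjusted p was 1.10e-05 for fatty acid oxidation, 0.00352 for branched-chain amino acid catabolism and for the tricarboxylic acid cycle, 2.93e-06 for ribosomal proteins and for fast fibres, 0.000420 for glycolysis and 0.000726 for interferon. With an estimated correlation the adjusted p = 0.682 for the tricarboxylic acid cycle and 0.615 for the others. Over all genes 0 members passed, and adjusted over the list alone only Myoz1 did. Without dairy array 1 the medians of 0.26 for fatty acid oxidation, 0.14 for branched-chain amino acid catabolism, 0.08 for the tricarboxylic acid cycle, −0.12 for glycolysis and −0.18 for interferon were not past the camera threshold. The same held for branched-chain amino acid catabolism at 0.19 and the tricarboxylic acid cycle at 0.12 without leucine array 1, and for glycolysis at −0.12 without leucine array 2. Without dairy array 2 the medians were 0.73 for fatty acid oxidation, 0.22 for the tricarboxylic acid cycle and −0.60 for interferon, and without leucine array 2 the tricarboxylic acid cycle median was 0.22. Ribosomal and fast-fibre genes were past it whichever array was left out, at −0.11 and −0.15 without dairy array 1. Draws without an effect that used all 6 arrays had a median as far from 0 in 17 of 100 for fatty acid oxidation, 13 for branched-chain amino acid catabolism, 19 for the tricarboxylic acid cycle, 6 for ribosomal proteins, 12 for glycolysis, 6 for fast fibres and 7 for interferon. With these 4 arrays alone the counts were 3, 0, 11, 4, 2, 5 and 6 in the same order. Slow-fibre genes, which belong to oxidative fibres, moved the same way as fatty acid oxidation, higher with leucine in 12 of 14 with a median of 0.27. That list was not past the camera threshold with all 6 arrays, with an adjusted p of 0.350, and was past it with the 4 leucine and dairy arrays alone, with 0.0109, against 0.571 with an estimated correlation on the same 4 arrays. Draws had a slow-fibre median as far from 0 in 84 of 100 with 6 arrays and in 9 of 100 with 4. Whether a difference in fibre type carried the metabolic lists was not tested.

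Fndc1, a fibronectin type III domain gene, was 4.02-fold lower with leucine than with dairy (−2.01 ± 0.19), Vim, the intermediate filament vimentin, stood at −0.85 ± 0.11, Ly6e at −1.01 ± 0.10 and Ache at −0.58 ± 0.06. Akr1b10, an aldo-keto reductase, was 2.39-fold higher (1.26 ± 0.15), and Nqo2 stood at 0.85 ± 0.07, Kcnma1 at 0.62 ± 0.08 and Slc38a9 at 0.53 ± 0.06, the latter past adjusted p 0.05 when adjusted over the list alone. By limma 0 of 14506 genes passed, with a lowest adjusted p of 0.514 and also 0 at an adjusted p of 0.10. An unadjusted p under 0.05 was found for 827 genes (327 higher, 500 lower) against 725.3 by chance. That count was 1095 with only the 4 leucine and dairy arrays and 721 after quantile normalization, with 0 past the threshold in each. In all 106 genes differed over 2-fold (24 higher, 82 lower), and the arrays did not overlap in 28.3% of genes, where chance gives 33.3%. Camera called 10 of 34 lists (3 up, 7 down), camera with an estimated correlation 0 and fry 1. Of 100 draws without an effect on 6 arrays, simulated for leucine against casein, 54 had 10 or more calls. With only the leucine and dairy arrays camera called 16 lists, and 0 with an estimated correlation, and 0 of 100 draws without an effect on these 4 arrays called as many as 16. The 6 lists added were slow fibres, mitochondrial biogenesis at 0.11 and hepatocytes at 0.48, which were higher with leucine, and circadian clock, immediate early and endothelial genes, which were lower. With an estimated correlation on the same 4 arrays their adjusted p was 0.571 for slow fibres, immediate early and endothelial genes, 0.632 for mitochondrial biogenesis, 0.778 for hepatocytes and 0.551 for the clock. Draws with 4 arrays had a median as far from 0 in 56 of 100 for hepatocytes, 27 for immediate early genes, 21 for mitochondrial biogenesis, 9 for slow fibres and 0 for the clock and endothelial lists.

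The responses to leucine and to dairy, each against casein, were then compared across genes, which are not independent replicates. Their fold changes had a correlation of 0.661 and the same sign in 70.2% of genes. Thbs1, Asrgl1, Prkx and Slc6a8 were among the genes with the smallest p in both comparisons, in the same direction in each. Simulated unchanged diets that shared the casein arrays gave a correlation of 0.502 and 66.6% of genes with the same sign from the pooled variances. With the variance of the casein arrays themselves the simulated correlation was 0.636 and the observed covariance of 0.0555 was below the simulated 0.0571. When each diet was compared with a different casein array the correlation was −0.00583. At an unadjusted p under 0.05, 182 genes were higher in both, where 17.2 are expected of independent lists, and 210 lower in both, where 16.2 are expected. The shared casein arrays raise these overlaps without any effect, so they were not taken as a response common to both diets.

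In 15 of the 34 lists no comparison passed the camera threshold with all 6 arrays, and their median log2 fold changes follow in the order leucine against casein, dairy against casein and leucine against dairy. The medians were 0.09, −0.03 and 0.05 for fatty acid and triglyceride synthesis, −0.02, −0.01 and −0.02 for cholesterol synthesis and uptake, 0.12, 0.07 and −0.06 for insulin signalling, and −0.0047, 0.04 and −0.04 for proteasome subunits. Immediate early genes had −0.39, −0.22 and −0.11, glucocorticoid-responsive genes −0.12, −0.08 and 0.00, oxidative stress and NRF2 targets 0.0021, 0.09 and −0.05, and heat shock and unfolded protein response genes 0.14, 0.02 and 0.09. Cell cycle genes had 0.0020, 0 and 0.0044, adipocyte markers −0.37, −0.06 and −0.31, erythroid markers 0.08, 0.03 and 0.08, smooth muscle and pericyte markers −0.03, 0.11 and −0.07, and satellite cell and regeneration genes 0.05, 0.01 and 0.02. The circadian clock and endothelial lists are the other two. In 11 of the 102 list tests the median, the mean and the direction of the test differed in sign, and 0 of these were past the threshold.

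Several of these lists depended on which casein array was used by camera with the preset correlation, while with an estimated correlation 0 lists passed against casein when either casein array was left out. Glucocorticoid-responsive genes had medians of 0.45 with leucine and 0.37 with dairy without casein array 2, past the preset threshold with adjusted p of 0.0103 and 0.00803, against 0.765 and 0.761 with an estimated correlation. Their medians without casein array 1 were −0.87 and −0.61, past the preset threshold in the other direction, with 0.468 and 0.529 by the estimated correlation. Immediate early genes had 0.08 with leucine and 0.33 with dairy without casein array 2, of which the second passed with an adjusted p of 0.0123, against 0.761 with an estimated correlation. They had −0.61 and −0.66 without casein array 1, past the preset threshold, with 0.262 and 0.380 by the estimated correlation. Satellite cell and regeneration genes had 0.40 and 0.35 without casein array 2, with preset adjusted p of 0.0424 and 0.0473 against 0.792 and 0.818 by the estimated correlation. Heat shock genes then had 0.23 and 0.09 and fatty acid and triglyceride synthesis genes 0.24 and 0.11. Both lists were past the preset threshold for leucine only, with adjusted p of 0.00918 and 0.0424, against 0.765 for each with an estimated correlation. In draws without an effect on all 6 arrays the preset correlation called the immediate early list in 54%, the satellite list in 53%, the glucocorticoid list in 50%, the heat shock list in 20% and the synthesis list in 0%. With both casein arrays, 92 of 100 draws for leucine and 100 for dairy had a satellite median as far from 0.

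Not past the threshold without casein array 2 were insulin signalling at −0.02 and 0.13, proteasome subunits at −0.01 and 0.03, oxidative stress and NRF2 targets at 0.02 and 0.10 and adipocyte markers at −0.21 and −0.0060. The same held for erythroid markers at 0.07 and −0.02, smooth muscle and pericyte markers at −0.13 and 0.03, cholesterol synthesis at −0.0049 and 0, and cell cycle genes at 0 and −0.0042. Of the lists described earlier, 3 passed by the preset correlation in a comparison with casein without casein array 2 and not with both casein arrays. The first was macrophage markers for dairy at 0.18, with an adjusted p of 0.761 by the estimated correlation. Its median was −0.04 with both casein arrays and −0.40 without casein array 1, past the preset threshold in the other direction, with 0.380 by the estimated correlation. The others were glycolysis at −0.16 and atrophy at 0.22 for leucine, each with 0.765 by the estimated correlation, where the medians with both casein arrays were −0.07 and 0.10. The preset correlation called the macrophage list in 61% of draws without an effect, glycolysis in 35% and atrophy in 0%.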

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

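The matrix tests below were set before their results were seen, on a pattern found in these data, and the draws without a diet effect were chosen after the result was seen. The results below stand out because leucine and dairy differed in the direct test of 1 diet against the other, by camera with the preset correlation. In each list this call was lost with an estimated correlation, a form whose power was not tested. Of the 10 lists called, 5 kept the call whichever array was left out. Of 100 draws without an effect on 6 arrays, simulated for leucine against casein, 54 had 10 or more calls.

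Matrix genes had a median log2 fold change of −0.85 with leucine against dairy, a fold computed from the leucine and dairy arrays alone. Scaling differences left between the deposited arrays are argued against as its source by the median of −0.76 that was left after quantile normalization. The deposited array medians already lay between 3.46 and 3.56, so this second normalization could move little. It cannot judge the authors' own normalization, whose method was not given. Fewer fibroblasts in the leucine pieces stays open as a candidate explanation. A set of 14 fibroblast genes chosen as constitutive, 3 of them also in the matrix list, had a median of −0.66 with 13 lower. The SE of their mean over genes, which are not replicates, was 0.12, and the median of 12 matrix genes was −1.13. The first median is only narrowly past the 0.5 times the matrix shift that had been asked for. Several of the 14, such as Dcn, Lum and Mfap5, encode matrix proteins themselves. The set therefore cannot separate fewer fibroblasts from lower matrix synthesis per cell. An effect of the diets on the connective tissue of muscle also stays open, as untested.

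Macrophage and leukocyte markers had a median of −0.55, lower with leucine in 22 of 23 genes. Fatty acid oxidation genes had a median of 0.45, higher with leucine in 30 of 31 genes. Interferon-response genes had a median of −0.34, lower with leucine in 23 of 26 genes. Calcium-handling genes had a median of −0.27, and they were the 1 list that fry also called. Fast-fibre contractile genes had a median of −0.27, lower with leucine in 14 of 15 genes. Branched-chain amino acid catabolism genes had a median of 0.23, higher with leucine in 18 of 23 genes. Cytosolic ribosomal protein genes had a median of −0.18, lower with leucine in 53 of 67 genes. Glycolysis genes also had a median of −0.18, lower with leucine in 22 of 28 genes. Tricarboxylic acid cycle genes had a median of 0.14, higher with leucine in 16 of 20 genes. Without dairy array 1 the fatty acid oxidation, branched-chain, tricarboxylic acid cycle, glycolysis and interferon lists were not past the camera threshold. In that order, 17, 13, 19, 12 and 7 of 100 draws without an effect on 6 arrays had a median as far from 0. With the 4 leucine and dairy arrays alone the counts were 3, 0, 11, 2 and 6.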

How the results depend on the processing

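The alternatives here were set before the data were examined, and the draws described with the processing and the estimated correlation on fewer arrays were chosen after the result was seen. The count of genes past the threshold was 0 in all 3 comparisons under every alternative that kept all 6 arrays, with only the 4 compared arrays, at an adjusted p of 0.10 and with the replicate block. With single arrays left out it was between 0 and 1 for leucine against casein and for dairy against casein, where the 1 was Il6 without casein array 1, and 0 for leucine against dairy. Of 165 gene fold changes followed, 149 kept their sign under every alternative. The list counts depended most on the test. With an estimated correlation they were 0, 0 and 0 for leucine against casein, dairy against casein and leucine against dairy, and with fry 0, 2 and 1. On fewer arrays the estimated correlation also gave 0 in each comparison with only the 4 compared arrays, without casein array 1 and without casein array 2. For dairy against casein the count of 14 was 7 after quantile normalization, 6 with the brighter genes alone and 9 with the 4 compared arrays, and for leucine against dairy the count of 10 was 16 with the 4 compared arrays. With single arrays left out the counts ran between 10 and 15, between 8 and 18 and between 6 and 16. With the replicate block, although the numbers did not pair the samples, they were 15, 12 and 11. The brighter genes are fewer and leave shorter lists, too short for a value in the Schwann cell, cell cycle and erythroid lists. For the other alternatives the cause was not tested.

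The correlation of the responses to leucine and dairy was −0.00583 with the casein arrays split between them, which removes the shared controls by construction, and between 0.492 and 0.860 with single arrays left out. The hepatocyte percentile stayed within its spread between arrays, between 46.9 and 53.1 with single arrays left out. With arrays centred on their medians Bckdha was 0.0034 for leucine against casein and 0.0066 for dairy against casein. After quantile normalization Bckdk was −0.089, the fast-fibre list −0.021 and the mTORC1 list −0.025 for dairy against casein. The cause was not tested.

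With single arrays left out, genes and lists that changed sign or direction of test had these ranges of log2 fold change for leucine against casein. They were −0.83 to 0.015 for Bcat2, −0.24 to 0.12 for Bckdha, −0.35 to 0.10 for Bckdk, −0.23 to 0.76 for Irs1, −0.062 to 0.72 for Cpt1b, −0.012 to 0.70 for Fbxo32, −0.73 to 0.33 for Trim63 and −4.56 to 0.40 for Il6. The slow-fibre list ranged from 0.062 to 3.66 and the inflammatory list from −0.82 to 0.0086. For dairy against casein they were −0.22 to 0.14 for Bckdha, −0.28 to 0.34 for Bckdk, −0.076 to 0.32 for Ppargc1a, −0.098 to 0.69 for Cpt1b, −0.34 to 0.77 for Ucp3, −0.43 to 0.28 for Fbxo32, −0.61 to 0.45 for Trim63 and −4.82 to 0.14 for Il6. Among lists they were 0.0018 to 0.22 for fast fibres, −0.18 to 3.10 for slow fibres, −0.097 to 0.00075 for ATF4, 0.015 to 0.43 for oxidative phosphorylation, 0.026 to 0.28 for the tricarboxylic acid cycle, −0.11 to 0.77 for fatty acid oxidation and −0.64 to 0 for inflammation. An end of each list range fell without casein array 2, except fast fibres, where the lowest median fell without dairy array 1, and the cause was not tested.

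Of the other values for lists called with all arrays, 127 kept their direction and call and 98 kept the direction without the call, 2 turning, and with single arrays left out the numbers were 165, 54 and 9. Signal over background could not be assessed, since background readings were not used here.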

Other observations

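The genes named in this part were chosen after their values were seen, as were the tests of the slow-fibre and hepatocyte patterns. Circadian clock genes were lower with leucine than with dairy in 11 of 16, with a median log2 fold change of −0.27, and their medians were −0.21 for leucine against casein and −0.02 for dairy against casein, or −0.20 and 0.07 without casein array 2. Nr1d1, a repressor in the core clock, stood at 5.86 and 6.11 on the leucine arrays, 8.14 and 7.88 on the dairy arrays and 7.46 and 6.81 on the casein arrays. Its log2 fold change between leucine and dairy was −2.02 ± 0.26 (SE), with an adjusted p of 0.514 over all genes and 0.0157 adjusted over the list alone. The clock genes Bhlhe40 and Tef stood at −1.10 ± 0.32 and −0.42 ± 0.11. The list had a camera adjusted p of 0.0545, or adjusted p = 0.615 with an estimated correlation, and passed the threshold with the 4 leucine and dairy arrays alone, where the adjusted p = 0.551 with an estimated correlation. In draws without an effect 0 of 100 had a median as far from 0. The labels give no time of day for the sampling.

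Endothelial markers had medians of 0.07 for leucine against casein, 0.22 for dairy against casein and −0.22 for leucine against dairy, and the list passed the camera threshold in none of the 3 with all 6 arrays. Without casein array 2 the medians against casein were −0.09 for leucine and 0.03 for dairy. With only the leucine and dairy arrays the list was past the threshold for leucine against dairy, with an adjusted p of 0.00687, or adjusted p = 0.571 with an estimated correlation on the same arrays. Draws without an effect had a median as far from 0 in 0 of 100 with these 4 arrays and in 7 of 100 with all 6. Emcn stood at 0.59 ± 0.06 for dairy against casein and at −0.34 ± 0.06 for leucine against dairy, with adjusted p of 0.00447 and 0.0415 adjusted over the list alone. Among heat shock genes, Hspe1, a mitochondrial chaperonin, stood at 1.20 ± 0.22, Hsph1 at 0.69 ± 0.11 and, in the other direction, Calr at −0.44 ± 0.08 for leucine against dairy, each with an adjusted p of 0.0461 adjusted over the list alone. Actc1, the cardiac actin gene that developing and regenerating muscle expresses, stood at 2.72 ± 0.38 for leucine against casein, with an adjusted p of 0.0280 adjusted over the list alone. Pmp22 stood at −1.25 ± 0.18 for leucine against dairy, with 0.0208. In all, 17 list members passed adjusted over the list alone for leucine against casein, 1 for dairy against casein and 25 for leucine against dairy, and 0 passed over all genes.

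On casein array 2 several transcripts of acute inflammation and stress lay far above the other 5 arrays. Il6 stood at 6.97, against 2.0 to 2.40 on the others, Ccl2 at 7.97, against 3.47 to 3.77, and Socs3 at 7.71, against 3.53 to 4.59. The immediate early genes Fos and Junb stood at 7.48 and 9.19, with at most 4.79 and 5.59 elsewhere. The metallothionein gene Mt1 stood at 11.2, against 6.45 to 7.53.

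The slow-fibre genes were low on casein array 2, where Myh7, the slow myosin heavy chain, stood at 6.07, against 10.7 to 11.4 on the other arrays, and Tnnc1 at 4.46, against 9.60 to 10.5. A tissue other than skeletal muscle is argued against by the fast-fibre list, whose median was −0.088 relative to the other 5 arrays, beside −3.42 for the slow-fibre list. The lowest fast-fibre member, also at −3.42, was Myh2, the myosin of oxidative fast fibres. The fast-fibre list, at a level of 12.4 against 9.02 for slow fibres, cannot alone judge a fault of the signal or normalization. Nearer in level were ribosomal proteins (8.77), oxidative phosphorylation (9.03) and fatty acid oxidation (8.74). Relative to gene means they had −0.03, −0.37 and −0.81 on this array, against −2.85 for slow fibres. This argues against a fault that lowered all genes of that level alike. A piece with few slow fibres, from another part of the muscle or another fast muscle, stays open: 14 of 14 slow-fibre members were lowest on this array, a count that restates the pattern. No biological explanation from the design was tested, since both casein arrays had the same diet.

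Hepatocyte transcripts differed between arrays of the same diet, with list medians of 0.02 and 1.94 on the casein arrays, −0.40 and −0.98 on the dairy arrays and −1.0 and 0.58 on the leucine arrays relative to the gene means. Alb, the albumin gene, stood at 9.48 and 11.7 with casein, 8.11 and 5.54 with dairy and 4.81 and 9.80 with leucine, while fast-fibre genes stood at 12.4. An acute-phase reaction of the muscle itself as the whole source is argued against on the casein arrays alone. There 7 liver enzymes of the list that are not plasma proteins were higher on array 2 than on array 1 by a median of 1.70 (SD 0.70). On the leucine arrays, array 2 minus array 1, their median difference was 0.17 (SD 0.66), and on the dairy arrays, array 1 minus array 2, 0.25 (SD 0.28). Their median level on the higher array was then 3.20 and 2.94, below the median gene, so they decide nothing for these diets. Liver RNA carried into some samples stays open on every diet. Another 23 liver genes outside the list had median differences of 0.39 (SE 0.15) for casein, 0.24 (SE 0.10) for leucine and 0.041 (SE 0.052) for dairy. Each SE is that of the mean over these genes, which are not replicates. No median was above 0.5, the value asked for, and their levels also lay below the median gene. On the leucine and dairy arrays the median levels of both the 7 enzymes and the 23 genes lay below the median gene. These 2 medians therefore cannot tell carried-over liver RNA from a reaction of the muscle there. A biological explanation was not tested, since arrays of the same diet differed.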
